A study of Mus musculus with 6 samples.

How the data were processed

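RNA from 6 cell populations sorted from tumours was analysed, 2 Elf5-positive and 4 Elf5-negative by the labels. Tumours were digested with collagenase and hyaluronidase and sorted with CD45, CD31 and TER119 antibodies and then by GFP, per the labels' protocols. The deposited table holds whole-number estimated counts (expected counts) for 52325 Ensembl genes, made by the authors with Salmon on mouse build GRCm38.p5, per the submitters' processing notes. The Salmon version, the annotation release and how transcripts were summed and rounded to genes are not given in the sources used here. Estimated counts share reads between similar genes by model, so values of genes with near-identical copies are less certain.

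Gene symbols were matched for 52220 IDs, and 77 IDs that shared a symbol with an ID of larger total kept their ID as name. Coordinates came from GENCODE M21 (GRCm38). The deposited counts are whole numbers, so rounding changed none. Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and rtracklayer 1.62.0, and figures Python 3.11.15 with matplotlib 3.10.9. Low counts were removed with filterByExpr by group, which left 20684 genes, and libraries were scaled with TMM factors. Elf5-positive and Elf5-negative libraries were compared with edgeR's quasi-likelihood test with no block and a Benjamini-Hochberg adjusted p below 0.05. Standard errors are the log2 fold change divided by the root of the F statistic. CPM are TMM-scaled. The common biological coefficient of variation was 0.446. Totals ran from 9106660 to 53694884 counts, so the shallowest library limits the precision of low genes, and intervals cover counting error only.

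Before the data were examined, 16 gene lists and 11 lists of markers of other cell types were fixed and tested with limma's camera on log2 CPM (prior count 3, inter-gene correlation 0.01), adjusted over each kind, with the estimated correlation beside. None of the 9 lists called held with an estimated correlation. The genes to be named were also fixed then. They are Elf5, 11 genes of interest to the study, the 10 genes with the largest and the 10 with the smallest log2 fold change among those that passed, had an average log2 CPM of at least 1 and no overlap between groups, and up to 4 members of smallest p of each list. Predicted genes, Rik clones, immunoglobulin and T cell receptor segments and IDs with no symbol were left out of the 10. A few genes that this rule names are not given here. Members are named here for the 16 lists and for the marker lists that passed. Genes of chromosome 6 were chosen after seeing the data.

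The test was tried on 5 sets of simulated counts with 200 genes changed in each, drawn from genes with an average log2 CPM of at least 1. It recovered 223 of 250 genes raised by 3 on the log2 scale, 169 of 250 lowered by 3, 8 of 250 raised by 1 and 4 of 250 lowered by 1, and 42 of its 446 calls were false. Camera called the lists of changed genes in all 5 sets and 0 of 70 lists of unchanged genes. Simulated genes were drawn independently, so this does not test camera on correlated genes. The estimated correlation of the real fibroblast and endothelial lists was 0.51 and 0.81. Alternatives were other normalization factors, other low-count filters, robust dispersions, DESeq2, limma-voom, the title number as a block, T2 libraries only and each library left out. Thinning to the smallest total, scaling to epithelial genes and leaving out Elf5-negative libraries 1 and 2 were added after seeing the data.

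For chromosome 6, genes with a mean of at least 20 CPM were compared within the 2 pairs of T2 libraries that share a title number. A gene counted as specific to a pair where it lay at least 1 above every library outside the pair on the log2(CPM + 1) scale. The first definition asked this of both libraries of the pair, took the raw ratio and began at 135 Mb. After its result was seen it was widened to 8 definitions (distal or whole chromosome, both libraries or the Elf5-positive one, raw ratio or ratio of the excess over the other libraries). The reasons were that it held 1 gene in the pair of Elf5-positive library 2, too few for its test to pass, and that it selected on the Elf5-negative library. The 4 definitions that select on both libraries favour small ratios and were then left out of the verdict, after all 8 had been seen. Of the others, a definition was used where it held at least 5 genes, its quartiles did not lie beyond 0.25 on both sides of 0, and it picked genes more often in the region than elsewhere. Differences of medians were tested with 9999 permutations of genes, two-sided, and genes are not independent replicates.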

Results

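Gene expression was measured by RNA sequencing in cells sorted from breast tumours of C57BL/6 mice with the C3-T tumour background and an Elf5-GFP reporter. Green fluorescent protein (GFP) marks cells that express Elf5, an ETS-family transcription factor of luminal progenitor and alveolar cells of the mammary gland. Digested tumours were sorted with antibodies against CD45, CD31 and TER119 and then by GFP. There were 6 libraries, 2 of GFP-positive (Elf5-positive) and 4 of GFP-negative (Elf5-negative) cells. The sample titles carry a number, of which there are 2, and a code, T1 or T2, neither of which the labels define. Elf5-positive library 1 and Elf5-negative library 2 share a number and the code T2, and are called pair 1 here. Elf5-positive library 2 and Elf5-negative library 4 share the other number and T2, and are called pair 2. Elf5-negative libraries 1 and 3 are the T1 libraries, with the numbers of pair 1 and pair 2. Library totals were 9106660 counts in Elf5-negative library 4 and 32602477 to 53694884 in the other 5. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries.

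The comparison asks how Elf5-positive and Elf5-negative cells sorted from these tumours differ in gene expression. The Elf5-negative cells are not shown to be tumour cells only. Of 18 pan-luminal and epithelial genes 10 rose in the Elf5-positive libraries, and of 20 luminal progenitor genes 4 rose, Elf5 itself among them. Of 20 epithelial-mesenchymal transition genes 8 fell, of 18 basal and myoepithelial genes 10 fell, and of 14 fibroblast markers 12 fell. Elf5 itself (ENSMUSG00000027186.14, chromosome 2, 103411688 to 103450989, GRCm38) was at 107.3 ± 42.0 CPM (TMM-scaled; SD, n = 2) against 13.2 ± 7.84 CPM (SD, n = 4). Elf5-positive libraries 1 and 2 held 77.7 and 137.0 CPM, and Elf5-negative libraries 1 to 4 held 10.7, 6.93, 10.5 and 24.7 CPM. The log2 fold change of Elf5 was 3.04 with a standard error of 0.48 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0165). The sort selected on a reporter of this gene, so its difference checks the labels. The adjusted p of Elf5 was 0.0665 without Elf5-negative library 1, 0.0644 without Elf5-negative library 3 and 0.0573 without Elf5-positive library 2, with log2 fold changes of 2.96, 2.94 and 2.58. Scaled to epithelial genes, the log2 fold change of Elf5 was 1.54.

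Of 20684 genes tested, 121 were higher and 783 lower in the Elf5-positive libraries (edgeR, adjusted p below 0.05), so 86.6% of the called genes were lower. The values of the 2 groups did not overlap in any of the 904 called genes. Among all genes tested 25.7% had no overlap, where chance gives 13.3%. On simulated counts this test recovered 89.2% of genes raised by 3 on the log2 scale and 67.6% of genes lowered by 3. It recovered 3.2% and 1.6% of genes raised and lowered by 1. The changed genes had an average log2 CPM of at least 1, so recovery of genes below that level was not tested. In these simulations 9.42% of the calls were false, above the 5% that the threshold sets. With the title number as a block 252 genes were higher and 1011 lower, and in the T2 libraries with the block 549 and 1368. The T2 fit with the block rests on only 2 pairs, which leaves little to estimate the spread from. Its calls are therefore less certain, and the simulations covered no fit with a block. In the T2 libraries without the block edgeR called 0 in either direction (469 higher and 1463 lower at an unadjusted p under 0.05). There DESeq2 called 181 and 846. Higher genes numbered 25, 48 and 43 without Elf5-negative libraries 1, 2 and 3 and 39 without Elf5-positive library 2. Lower genes numbered 249 and 338 without Elf5-negative libraries 1 and 3 and 197 without Elf5-positive library 2. Of 56 named genes that passed, between 25 and 52 still passed with 1 library left out.

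The median log2 fold change of the 18 pan-luminal and epithelial genes was 1.56, and 10 of them rose (15 when adjusted over the list alone). Cldn7, a tight junction claudin, was at 207.4 ± 15.2 CPM (SD, n = 2) against 61.4 ± 9.41 CPM (SD, n = 4), a log2 fold change of 1.76 (SE 0.21). Rab25, a small GTPase of vesicle transport, Tjp3, of tight junctions, and the ETS factor Elf3 had log2 fold changes of 2.03, 2.01 and 2.07. The list passed camera at a preset correlation of 0.01 (adjusted p = 2.3e-13), but not with an estimated correlation (adjusted p = 0.246 with an estimated correlation). Of 20 luminal progenitor genes 4 rose (8 when adjusted over the list alone), namely Elf5, Lcn2 (log2 fold change 2.04), Wfdc18 (2.12) and Mfge8 (1.34). The sort selected on a reporter of Elf5, and the list was not tested without this gene. When scaled to epithelial genes Lcn2, Wfdc18 and Mfge8 were at 0.57, 0.67 and -0.17 and did not pass. Cldn7, Rab25, Tjp3 and Elf3 did not pass either, but they belong to the list that sets this scaling and are held near 0 by it. Of 18 named higher genes, these 4 included, 9 still passed. With TMM factors the luminal progenitor list's median was 1.15 (adjusted p = 2.5e-04, and adjusted p = 0.246 with an estimated correlation), and 0.73 without Elf5-positive library 2. Kit, the stem cell factor receptor on this list, had a log2 fold change of 2.09 (SE 0.71) and did not pass (adjusted p = 0.171), but passed with no low-count filter (0.0273), with DESeq2 (0.0337) and in the T2 libraries with the block (0.00575). Its groups overlapped, with 110.86 CPM in Elf5-positive library 1 and 139.45 CPM in Elf5-negative library 4. Scaled to epithelial genes, Kit was at 0.62 and did not pass. Tfap2c and Cd24a, on the hormone-sensing list, rose by 2.41 and 1.12 on the log2 scale, and Cd24a was at -0.39 when scaled to epithelial genes.

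The 28 cell cycle genes were shifted upwards as a list, with a median log2 fold change of 0.60 (camera adjusted p = 6.5e-08, and adjusted p = 0.246 with an estimated correlation). None of them passed with the settings chosen first (edgeR with TMM factors, the low-count filter, all libraries and no block), or when adjusted over the list alone. Mki67, a marker of proliferating cells, had a log2 fold change of 1.00 (SE 0.26, adjusted p = 0.0808), which was -0.53 when scaled to epithelial genes. Mki67 passed with DESeq2 (adjusted p = 0.0150) and in the T2 libraries with the block (adjusted p = 0.0390), where Cdc20 passed as well (log2 fold change 0.90, adjusted p = 0.0257). Scaling the libraries to the pan-luminal and epithelial genes in place of TMM moved the median log2 fold change of all genes from 0.05 to -1.47. With this scaling 17 genes were higher and 12153 lower. The cell cycle list had a median of -0.88 and no longer passed camera (adjusted p = 0.152), while the luminal progenitor list, with a median of -0.32, passed as higher relative to other genes (adjusted p = 8.0e-09). Outside the lists, Gpx2, a glutathione peroxidase, had a log2 fold change of 4.44 (SE 0.62). Other named higher genes, besides Elf5, were Nxf7, Rbp7, Hhipl2, Ppp2r2c, Ttc22, Sox14 and Tmprss13, with log2 fold changes from 2.71 to 3.41.

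**Figure D1:**
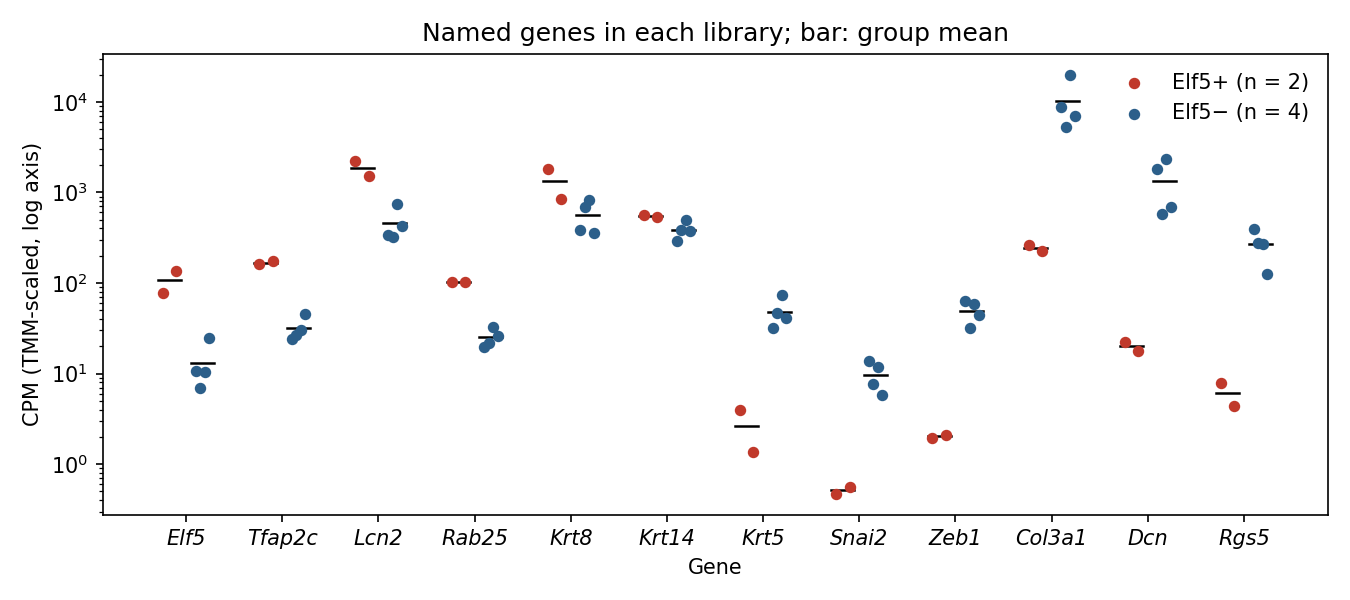
CPM (log axis) of 12 named genes in each library, with Elf5-positive libraries (n = 2) in red, Elf5-negative libraries (n = 4) in blue and a bar at each group mean. Elf5 lies at 77.7 and 137.0 CPM in the Elf5-positive libraries, above the 24.7 CPM of the highest Elf5-negative library.

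Of 20 epithelial-mesenchymal transition genes 8 fell in the Elf5-positive libraries (15 when adjusted over the list alone). Zeb1 and Zeb2, repressors of epithelial genes, had log2 fold changes of -4.61 (SE 0.40) and -3.80 (SE 0.28). Snai2, a repressor of the Snail family, was at 0.517 ± 0.0628 CPM (SD, n = 2) against 9.69 ± 3.58 CPM (SD, n = 4), a log2 fold change of -4.22 (SE 0.55). The list's median was -2.52 (camera adjusted p = 3.8e-14, and adjusted p = 0.143 with an estimated correlation). Markers of fibroblasts, which the sorting antibodies do not remove, moved with it. Of 14 fibroblast markers 12 fell (13 when adjusted over the list alone), with a median of -4.55 (adjusted p = 4.2e-17, and adjusted p = 0.158 with an estimated correlation). The fibrillar collagen Col3a1 was at 241.7 ± 26.5 CPM against 10256 ± 6532 CPM, and Dcn (decorin) at 20.1 ± 3.50 CPM against 1352 ± 855 CPM. Of 9 pericyte and smooth muscle markers 5 fell (8 when adjusted over the list alone), among them Rgs5 (log2 fold change -5.44) and Abcc9 (-4.91). Their median was -4.08 (adjusted p = 1.2e-09, and adjusted p = 0.158 with an estimated correlation). Of 12 markers of endothelial cells, which the CD31 gate should remove, Kdr, Tek and Eng fell (4 genes when adjusted over the list alone), with a list median of -1.21. Its adjusted p was 1.6e-04 (adjusted p = 0.667 with an estimated correlation), and 0.0948 without Elf5-positive library 2, with a median of -0.59; without Elf5-positive library 1 the median was -2.20.

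Of 18 basal and myoepithelial genes 10 fell (13 fell and 1 rose when adjusted over the list alone). The basal keratin Krt5 was at 2.67 ± 1.83 CPM (SD, n = 2) against 48.4 ± 17.5 CPM (SD, n = 4), a log2 fold change of -4.18 (SE 0.58). Krt14, its partner keratin, had a log2 fold change of 0.52 (SE 0.27, adjusted p = 0.407), which was -0.96, and passed, when scaled to epithelial genes. The list's median was -3.19 (camera adjusted p = 1.6e-07, and adjusted p = 0.275 with an estimated correlation). Its members Myh11 and Acta2, contractile genes of smooth muscle, stand on the pericyte list as well, and Snai2 on the epithelial-mesenchymal transition list. Of 22 chemokine and myeloid growth factor genes 5 fell (7 when adjusted over the list alone), including Il33 (log2 fold change -5.05), Il6 (-4.63) and Il34 (-2.43). The list's median was -1.11 (adjusted p = 2.5e-04, and adjusted p = 0.438 with an estimated correlation). Without Elf5-positive library 2 its adjusted p was 0.0543, and in the T2 libraries its median was -0.44. Of the 10 named lower genes, C7, Abca8a, Ifi205, Scg3, Ptgir, Ces2g and Cacng7 had log2 fold changes from -7.36 to -6.23. C7 and Cacng7 averaged only 0.061 and 0.043 CPM in the Elf5-positive libraries, so their fold changes rest on few counts there. Fgf23, Ccl19 and Pcdh20 had 2, 3 and 3 counts over both Elf5-positive libraries, with pooled ratios, Elf5-negative over Elf5-positive, of 215.6, 111.3 and 127.8. The exact 95% intervals of these ratios were 59.4 to 1784, 37.9 to 541.7 and 43.5 to 621.4, and cover counting error only.

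**Figure D2:**
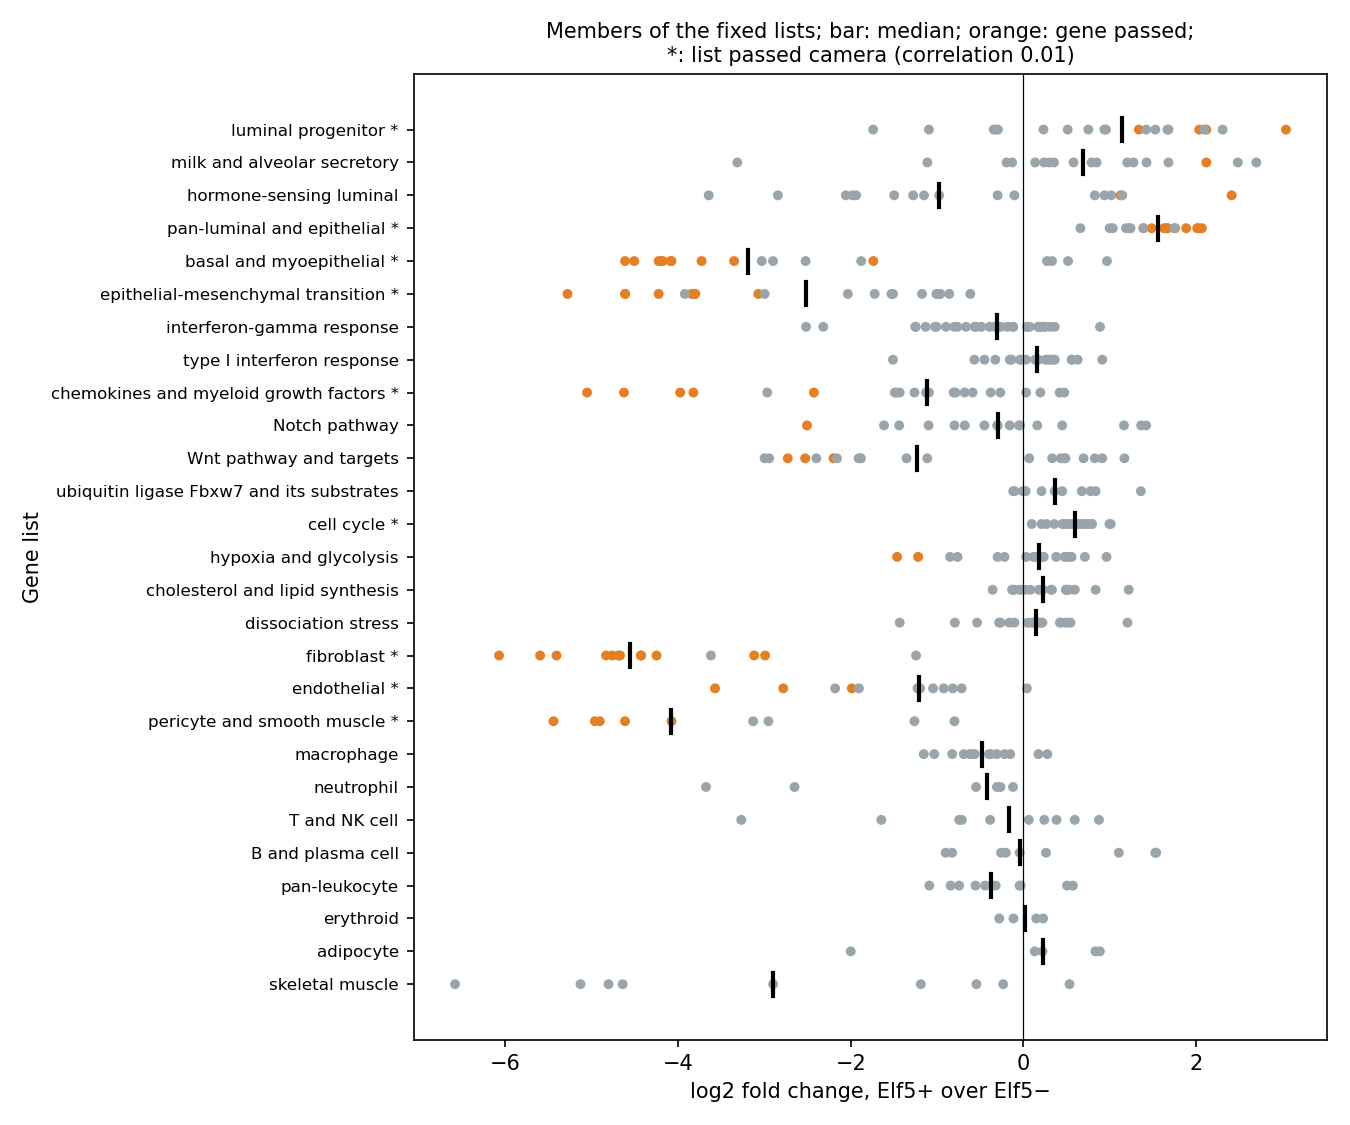
Log2 fold change (Elf5-positive over Elf5-negative) of each tested member of the 27 fixed lists, with a bar at each list's median, genes that passed in orange and lists that passed camera at a correlation of 0.01 starred. The pan-luminal and epithelial median lies at 1.56 and the fibroblast median at -4.55; scaling to epithelial genes moves them to 0.08 and -6.06.

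The receptor chains Ifngr1 and Ifngr2 had log2 fold changes of -0.57 (SE 0.28) and -0.31 (SE 0.35), and Cd274, which encodes PD-L1, had one of -1.13 (SE 0.54), and none of these passed. Without Elf5-positive library 2 Ifngr2 was at 0.068. Scaled to epithelial genes, which lowers the median of all genes, Ifngr1, Ifngr2 and Cd274 passed in edgeR, with log2 fold changes of -2.08, -1.85 and -2.71. Fbxw7, a substrate receptor of a ubiquitin ligase, had a log2 fold change of 0.78 (SE 0.30, adjusted p = 0.228) and the luminal keratin Krt8 of 1.24 (SE 0.45, adjusted p = 0.201), which were -0.71 and -0.26 when scaled to epithelial genes. Krt8 is on the list that sets this scaling, and passed in the T2 libraries with the block (adjusted p = 0.0160). The oestrogen receptor Esr1 had a log2 fold change of -1.15 (SE 0.50, adjusted p = 0.293), and passed at -2.65 when scaled to epithelial genes. The median of the 35 interferon-gamma genes was -0.31 (camera adjusted p = 0.0966), and none of them passed with the settings chosen first or when adjusted over the list alone. With other settings the list passed as lower in 2 of 18, Cxcl9 passed with no low-count filter (log2 fold change -2.58, adjusted p = 0.0326) and with DESeq2, and Jak1 passed in the T2 libraries with the block (-0.77, adjusted p = 0.0391). Both passed when scaled to epithelial genes, as did Jak2 and Irf8.

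The other lists that did not pass camera had medians of -0.98 (hormone-sensing), -0.30 (Notch pathway) and -1.23 (Wnt pathway). The medians were 0.68 for milk and alveolar secretory genes, 0.15 for type I interferon, 0.36 for Fbxw7 and its substrates, 0.18 for hypoxia and glycolysis, 0.22 for cholesterol and lipid synthesis and 0.14 for dissociation stress, all of which lay below 0 when scaled to epithelial genes. Of 18 other settings at the preset correlation, the milk list passed as higher in 8, Fbxw7 and its substrates in 6, cholesterol in 4 and hypoxia in 1, and the Wnt list as lower in 5. Among these, when scaled to epithelial genes the milk list had a median of -1.07 and passed as higher relative to other genes (adjusted p = 6.4e-08). Within the lists of this paragraph Axin2, Apcdd1 and Wnt10a of the Wnt list fell, with log2 fold changes of -2.53, -2.73 and -2.20 (6 fell and 2 rose when adjusted over the list alone). Heyl of the Notch list fell (-2.51; 1 fell when adjusted over the list alone), as did Adm and Hk2 of the hypoxia list (-1.46 and -1.22; 2 fell and 1 rose). On the hormone-sensing list 3 rose and 2 fell when adjusted over the list alone, and on the milk list 1 rose. Markers of the cells that the CD45 and TER119 gates should remove did not pass with the settings chosen first, with medians of -0.48 for macrophages, -0.43 for neutrophils, -0.16 for T and NK cells, -0.04 for B and plasma cells, -0.37 for all leukocytes and 0.02 for erythroid cells. The B and plasma cell list has a median, and the erythroid list a mean, opposite in sign to its test. When scaled to epithelial genes the B and plasma cell list, with a median of -1.70, passed as higher relative to other genes (adjusted p = 1.6e-04), and without Elf5-positive library 1 the macrophage list passed as lower (adjusted p = 0.0442). Adipocyte and skeletal muscle markers had medians of 0.22 and -2.90 and did not pass, though skeletal muscle passed as lower in 2 of 18 other settings; the erythroid and adipocyte medians were -1.50 and -1.23 when scaled to epithelial genes. Mean skeletal muscle marker levels were 24.2 CPM in Elf5-negative library 1 and 4.95 CPM in library 2, against at most 1.69 CPM in the other 4. Without these 2 libraries edgeR called 0 genes higher (539 at an unadjusted p under 0.05, 130 by DESeq2) and 75 lower (1657 and 1102).

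Some transcripts of distal chromosome 6 were far more abundant in pair 1, or in another library, than in the rest. These genes were chosen after their values were seen. Wbp11 (chromosome 6, 136813654 to 136828233, GRCm38) was at 1652 and 1197 CPM in the 2 libraries of pair 1 and at most 232.9 CPM in the other 4. Lmntd1 (145365134 to 145614319) was at 233.1 and 130.7 CPM in pair 1 and at most 1.13 CPM elsewhere. Aebp2 (140622663 to 140678472) was at 1315 CPM in Elf5-negative library 1 and at most 431.8 CPM elsewhere. None of these 3 genes passed between the sorts in edgeR. Pair 2 shared raised genes of chromosome 6 as well. Cdkn1b (134920401 to 134925513) was at 459.3 and 333.1 CPM in pair 2 and at most 110.7 CPM elsewhere.

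**Figure D3:**
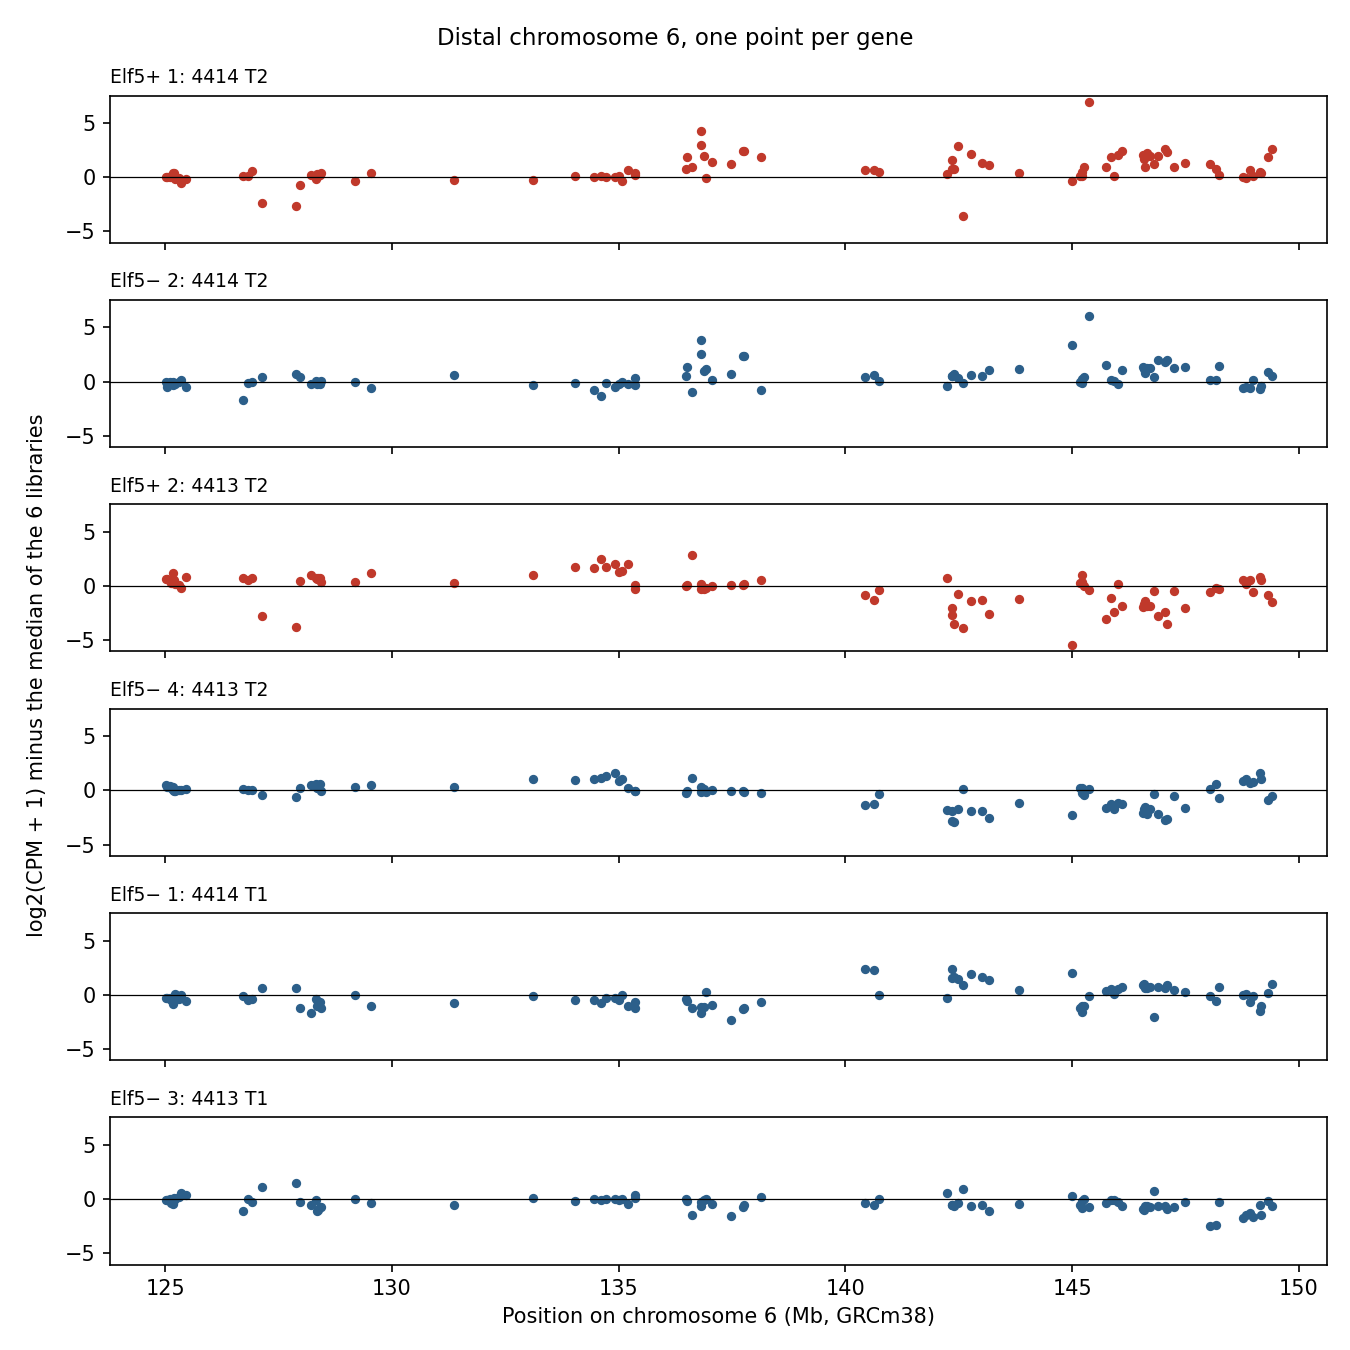
Genes of distal chromosome 6 (position in Mb, GRCm38) in each library, as log2(CPM + 1) minus the median of the 6 libraries, with Elf5-positive libraries in red and Elf5-negative libraries in blue. The 2 libraries of pair 1 share raised genes such as Wbp11 (1652 and 1197 CPM), which lies at 232.9 CPM or less in the other libraries.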

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

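The tests of the pericyte genes, of normalization, of dilution and of a shared tumour were chosen only after the result was seen. For depth the prediction was written before its result was seen, though thinning itself was added after seeing the data.

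Among 125 results checked in the 4 Elf5-negative libraries, 8 had 1 library far from the other 3. The ratio used was its gap to the nearest library over the whole range. For genes and list means this ratio was taken on the log2(CPM + 1) scale, so it differs from one taken on the CPM printed here. Chance gives about 1 in 20. Elf5-negative library 4 lay low for Tjp3 (ratio 0.866; 6.89 CPM against 8.92 to 9.28), Heyl (0.878; 13.99 CPM against 28.9 to 31.9) and the chemokine list mean (0.842; 57.7 CPM against 97.7 to 107.8). Elf5-negative library 2 lay high for Bub1b (0.875; 106.3 CPM against 84.5 to 87.0), Fdps (0.855; 153.0 CPM against 81.9 to 89.7) and the hypoxia and glycolysis list mean (0.895; 605.5 CPM against 300.3 to 323.2). Elf5-negative library 1 lay low for Ppp2r2c (0.83; 2.49 CPM against 6.75 to 8.13) and high for the pan-leukocyte list mean (0.926; 14.9 CPM against 7.14 to 7.55).

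Of 20 epithelial-mesenchymal transition genes 8 fell in the Elf5-positive libraries. Normalization as the whole cause is argued against. The epithelial-mesenchymal transition list kept its call, and its median moved by at most 0.271 with 2 other kinds of factors and limma-voom. That largest move was with limma-voom, which kept the TMM factors. With the 2 other kinds of factors the median was -2.50 and -2.49, and it was -4.07 when scaled to epithelial genes. Stromal cells in the Elf5-negative sort may contribute, which no antibody of the sort removes: the 6 pericyte genes on no other list had a median log2 fold change of -4.02, and Rgs5 was at 266.6 CPM in Elf5-negative and 6.14 CPM in Elf5-positive libraries. A mesenchymal state of the tumour cells stays open as well, with no test of it given here, and both may hold.

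Of 18 epithelial genes 10 rose in the Elf5-positive libraries. Suppose other cells only diluted tumour transcripts in the Elf5-negative sort, held none of the compared transcripts, and copy number were equal in both sorts. Then chromosome 6 genes specific to a pair would differ as much as epithelial genes do. These assumptions together are argued against in pair 1, where genes selected on the Elf5-positive library had a median log2 ratio of 0.80 to 0.86 against 1.64 for epithelial genes, a difference of at least 0.782 (permutation p 9e-04 and 0.0026); the distal and whole-chromosome definitions picked the same genes there, so only 2 of the 4 such definitions are distinct. In pair 2 it cannot be told apart: 2 of the 4 definitions could be used, with a difference of at least 0.438 (permutation p at most 0.0255), but an unused one with 4 genes gave -0.020. Equal copy number was not tested. Elf5-positive library 1 departed in 53 windows of chromosome 15 and 32 of chromosome 18, where Elf5-negative library 2 did in 0 and 0. These counts cannot decide copy number. They pool departures up and down from a median that includes the T1 libraries, which are all Elf5-negative. Dilution would also shrink departures in the Elf5-negative sort. Expression of the chromosome 6 genes in other cells was not tested either, and Wbp11 lay at 62.4 to 232.9 CPM outside pair 1. Such expression would lower the raw ratio under dilution alone. Dilution with unequal copy number, or by other cells that express these genes, stays open and may account for the difference in either pair.

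On the first principal component (47.1% of the variance) Elf5-negative library 4 lay 0.39 of the way from the other Elf5-negative libraries to the Elf5-positive mean. On the second component it lay at -79.3, with Elf5-positive libraries 1 and 2 at 98.0 and -46.2. Across genes its r was 0.9458, 0.9463 and 0.9544 with Elf5-negative libraries 1, 2 and 3, above its 0.9419 with Elf5-positive library 2. Its r with Elf5-positive library 1 was 0.9156, the lowest of the 4 Elf5-negative libraries. Its lower depth as the whole cause is argued against, since the share was 0.346 with all libraries thinned to its total. A tumour shared with an Elf5-positive library is a candidate explanation, since in 2 of the 2 pairs the Elf5-positive library correlated best with the Elf5-negative library of its pair (r across genes, which are not independent replicates, 0.945 and 0.942, against at most 0.920 and 0.900 with another), which 1 of 12 assignments of different libraries would give by chance. In pair 2 this correlation draws on the same values as the component, so it is not independent of the pattern. Elf5-negative library 2 is paired in the same way but lay at -54.3 on the first component, against -1.34 for library 4, so sharing alone leaves the difference between these libraries open.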

How the results depend on the processing

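Thinning, epithelial scaling and leaving out Elf5-negative libraries 1 and 2 were chosen after seeing the data; the cause of each change below was not tested, except that smaller sets of libraries have fewer samples. Of the results of named genes and lists that passed, 841 gene and 158 list comparisons with an alternative kept direction and call, 221 and 11 lost the call and 2 and 2 changed sign. Robust dispersions do not enter camera. Genes higher and lower numbered 273 and 1331 with no low-count filter and 401 and 1735 with DESeq2. With T2 libraries only edgeR gave 0 and 0 (469 and 1463 at an unadjusted p under 0.05; DESeq2 181 and 846), and with Elf5-negative libraries 1 and 2 left out 0 and 75 (539 and 1657; DESeq2 130 and 1102). Epithelial scaling gave 17 and 12153. Leaving out 1 library gave 25 to 133 higher and 197 to 811 lower genes, an Elf5 log2 fold change of 2.58 to 3.53, 3 to 6 higher lists, 2 to 4 lower lists and 2 to 4 marker lists. Elf5 was at 2.78 (adjusted p = 0.27) in T2 libraries only and 2.67 (0.0966) with libraries 1 and 2 left out. Higher lists numbered 5 with no filter, 6 with DESeq2, 5 with limma-voom and 5 with libraries 1 and 2 left out; lower lists numbered 5 with no filter. With an estimated correlation 0 higher, 0 lower and 0 marker lists passed. Without either Elf5-positive library the lone one left is assumed to vary like the other group. The depth of 9106660 counts in Elf5-negative library 4 limits genes with low counts.

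The labels do not define the title number, and there are only 2 pairs, so the T2 fit with the block has little to estimate the spread from. The simulations covered no fit with a block. With it as a replicate block 252 genes were higher and 1011 lower, and in T2 libraries with the block 549 and 1368. The block also holds the T1 library of a number together with its pair. Under the block the B and plasma cell median was 0.18 and the erythroid -0.18; in T2 libraries with the block these were 0.23 and -0.25, hypoxia -0.045 and type I interferon -0.022.

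Other medians that changed sign belong to lists that had not passed. B and plasma cell was 0.12 with the CPM filter, 0.60 with limma-voom, 0.29 in T2 libraries only and 0.52 with libraries 1 and 2 left out. Erythroid was -0.11 with the CPM filter, -0.18 with DESeq2, -0.23 with no filter, -0.26 in T2 libraries only, -0.30 thinned and -0.22 with libraries 1 and 2 left out. Adipocyte was -0.93 with the CPM filter and -0.83 thinned, and hypoxia -0.10 in T2 libraries only. With libraries 1 and 2 left out macrophage was 0.44, pan-leukocyte 0.18 and skeletal muscle 0.23. Leaving out 1 library gave ranges of -0.69 to 0.68 for B and plasma cell, -1.46 to 0.036 for T and NK cell, -0.080 to 0.55 for adipocyte, -0.26 to 0.23 for dissociation stress, -1.06 to 0.56 for erythroid, -0.17 to 0.49 for hypoxia, -1.04 to 0.061 for macrophage, -0.10 to 1.38 for milk, -0.51 to 0.054 for pan-leukocyte, -0.16 to 0.29 for type I interferon and -0.84 to 0.068 for Ifngr2.

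Epithelial scaling sets epithelial genes near 0 by construction and lowers the median of all genes to -1.47, so 24 named genes and 10 lists with smaller positive values changed sign. Of those that had passed, Cd24a became -0.39, Mfge8 -0.17, luminal progenitor -0.32 (camera adjusted p = 8.0e-09) and cell cycle -0.88 (0.152). The others were Bub1b -0.78, Cdc20 -0.52, Cdk1 -0.79, Dtx1 -0.17, Egln3 -0.58, Egr2 -1.04, Fbxw7 -0.71, Fdps -0.94, Gata3 -0.56, Hey1 -0.072, Hspb1 -0.38, Idi1 -1.07, Ier3 -0.97, Klf5 -0.79, Krt14 -0.96, Krt8 -0.26, Mki67 -0.53, Mycn -0.16, Oas1a -0.93, Rnf43 -0.38, Rtp4 -0.93 and Srebf1 -0.69, and the lists adipocyte -1.23, cholesterol -1.28, dissociation stress -1.44, erythroid -1.50, hypoxia -1.38, milk -1.07, type I interferon -1.33 and Fbxw7 and its substrates -1.16.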

Other observations

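The scan of the genome was chosen only after the result was seen. It used 10185 windows of 15 neighbouring genes, which overlap, so many windows can come from a single stretch. Departures of over 0.8 (log2), up or down, from the median over title number and T code were counted. Elf5-negative libraries 1, 2, 3 and 4 departed in 17, 20, 3 and 38 windows, all of them on chromosome 6. Elf5-positive library 1 did so in 143 windows, of which 43 were on chromosome 6, 53 on chromosome 15 and 32 on chromosome 18. Elf5-positive library 2 did so in 83 windows, of which 53 were on chromosome 6 and 14 on chromosome 3. The highest window of both libraries of pair 1 was the same, from 145365134 to 147073991 on chromosome 6, with medians of 1.91 and 1.26. Those of pair 2 overlapped on chromosome 6. They ran from 131364855 to 135244955 in Elf5-positive library 2 (median 1.42) and from 129533160 to 135084709 in Elf5-negative library 4 (0.965). RNA levels do not show copy number, and no DNA was analysed here.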
